A study of Mus musculus with 46 samples.

How the data were processed

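Messenger RNA was measured in 46 labelled samples of mouse bone marrow-derived macrophages, in 23 groups of 2, across 4 experiments with their own tables. Experiment 1 holds control cells at 0, 1 and 4 hr of lipid A and cells with ACBI1, BRM014 or BRDK98 at 4 hr; experiment 2 holds Arid1a f/f control cells at 0, 1 and 4 hr of LPS and Arid1a knockout cells at 1 and 4 hr; experiment 3 holds Pbrm1 f/f control cells at 0 and 4 hr of lipid A and Pbrm1 knockout cells at 4 hr; experiment 4 holds control cells at 0, 20 and 60 min of lipid A and the 3 compounds at 20 and 60 min. Perturbed cells without stimulus were not analysed here, so an effect on resting cells cannot be separated from one on the response. Per the labels, libraries were made with a stranded mRNA kit and read as 50 bp single ends. Per the submitters' processing notes, reads were aligned with STAR 2.5.3a to mm10, counted with HOMER and compared with DESeq2.

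The authors' deposited tables are 4 of TPM (reads per exon length scaled by the authors) and 4 of comparisons. Their comparison tables hold log2 fold changes made by the authors before deposit, with p-values and adjusted p-values as deposited from the authors' own test; these were used only where the authors' deposited table is named. The plan, made before the data were examined, was a count model if counts were deposited and limma if not. Because the tables hold TPM, no count model was used. In experiment 1, 1 TPM column matched to no sample: it carries the name of 4 hr control replicate 1, and all 24537 genes in it equal that library. Only the first copy was used, so 4 hr control replicate 2 of experiment 1 is not analysed here, 45 libraries were used, and that control group has n = 1.

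TPM times exon length divided by its smallest step gave whole reads within 0.1 read for 99.8% or more of low values, so reads could be recovered. Exonic reads per library numbered 7015043 to 21283270 in experiment 1, 9290661 to 12045940 in experiment 2, 18040339 to 25175590 in experiment 3 and 9869569 to 27527450 in experiment 4. Totals in the file headers were 8466037 to 25807517, 10347213 to 14058921, 21744715 to 29647009 and 11595035 to 31491682. At these depths 3 reads on a 2 kb transcript equal 0.065 to 0.298 TPM, and a listed 0 means below about that level. Near this floor the 1 added to TPM shrinks log2 changes and their intervals, so a small change there does not show similar levels. Listed TPM sum to 526364 to 658440 per library. Such floors cover counting error only.

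Genes with TPM of at least 1 in at least 2 libraries were tested: 11531, 11798, 11044 and 11549 in experiments 1 to 4, of 24537 or 25124 listed. Each experiment was fitted once with all its groups in limma 3.58.1 under R 4.3.3 on log2(TPM + 1), with trend and robust variance moderation, and with 5, 5, 3 and 9 residual degrees of freedom; p was adjusted by Benjamini and Hochberg within each of 26 contrasts and the threshold was 0.05. Replicates within groups differed with an SD of 0.178 to 0.444 on the log2 scale. The p-values measure spread between these samples; the labels do not say whether replicates were separate cultures or animals, so the spread may be technical. Tested on simulated data with the same group sizes, the fit recovered, of 100 genes changed by a fold of 2 and 100 by a fold of 4, 72 and 91 for ACBI1 at 4 hr (16 unchanged genes called), 93 and 92 for Arid1a loss at 4 hr (16), 80 and 95 for Pbrm1 loss (17) and 93 and 98 for BRDK98 at 20 min (2).

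TPM are shares of a total, so large increases in some transcripts can lower the TPM of others. Each fit was therefore repeated on TPM scaled by a median-ratio factor, an alternative added after the data were seen, and genes in lists and sets count as risen or fallen when both fits call them with the same sign. Named genes follow a rule: the targeted genes, 10 reference inflammatory genes, the 8 highest and 8 lowest called genes at 10 TPM or more whose groups do not overlap, and up to 4 called members of each list at 5 TPM or more. Stimulus contrasts take 5 highest and lowest, and differences between times or compounds 4. Reads were counted on both strands, so genes that overlap another annotated gene are less certain. The 22 gene lists were written before any value was seen and tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation. Induced sets are genes raised at least 1 on the log2 scale by the stimulus in controls of another experiment. Pairs of contrasts that share controls were set against 20 simulated draws of unchanged groups. Direct tests between compounds in experiment 4 were added later.

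Alternatives tried were a pseudocount of 0.1, no filter, limma without trend or robust moderation, a replicate block, leaving out each library, median scaling, limma voom on recovered reads, a minimum log2 change of 1, other induced sets and an estimated correlation. Count-model alternatives were planned for counts only and not run. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.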

Results

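Bone marrow-derived macrophages (BMDMs) from mice were stimulated with lipid A or LPS, both ligands of the receptor TLR4, while the SWI/SNF chromatin remodelling complex was perturbed with a compound or by loss of a subunit gene. ACBI1 is a degrader of the 2 SWI/SNF ATPases SMARCA2 and SMARCA4 and of PBRM1, BRM014 inhibits the ATPase activity of SMARCA2 and SMARCA4, and BRDK98 is known here by its code name only. Each value in brackets after a gene symbol is a log2 change ± its standard error, and each p beside it is adjusted over all tested genes. Genes given without p passed the test. The floor is 0.065 to 0.298 TPM. Counts adjusted over a list alone are given where they differ from all-gene counts. Groups hold 2 libraries, except 1 in the 4 hr lipid A control of experiment 1. Genes rose or fell if called so on both TPM as deposited and median-scaled TPM.

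In control macrophages of experiment 4, 15 of 23 immediate early and 14 of 30 primary NF-kB genes had risen by 20 min of lipid A, the first time sampled. Egr1 (5.12 ± 0.15), Fos (3.88 ± 0.13), Ier2 (3.87 ± 0.09) and the phosphatase gene Dusp1 (3.81 ± 0.10) rose, as did the chemokine gene Cxcl2 (3.83 ± 0.08) and the cytokine gene Tnf (3.10 ± 0.08, 159 ± 1.74 against 17.7 ± 1.61 TPM). Il10 (1.75 ± 0.21) and the prostaglandin synthase gene Ptgs2 (1.14 ± 0.20) had also risen. Il6 (0.08 ± 0.14, adjusted p = 0.779) and Ifnb1 (0.21 ± 0.15, adjusted p = 0.473), near the floor, did not pass. Of 23 measured immediate early genes 15 rose, 0 fell and 8 did not pass (19 and 0 adjusted over the list alone). Of 30 primary NF-kB inflammatory genes 14 rose, 0 fell and 16 did not pass (16 and 2 adjusted over the list alone). Luc7l3 (-0.97 ± 0.15) and Neat1 (-0.96 ± 0.21) were among the largest decreases. In all, 96 genes were higher and 62 lower at 20 min (93 and 44 after median scaling), and the authors' deposited table gives 191 and 420. The total was 538 without 0 min control replicate 2 and 54 without 20 min control replicate 2.

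By 60 min all 23 immediate early genes and 29 of 30 primary NF-kB genes had risen. Large increases included the interferon gene Ifnb1 (9.40 ± 0.15, 838 ± 212 against 0.22 ± 0.075 TPM), Cxcl2 (8.81 ± 0.08) and Tnf (8.25 ± 0.08). Il6 (5.38 ± 0.14), Il12b (5.16 ± 0.10), Il10 (5.71 ± 0.21) and Ptgs2 (6.37 ± 0.20) rose as well, and Nos2 (0.04 ± 0.11, adjusted p = 0.769), near the floor, did not pass. Among the decreases, Arrdc3 (-3.16 ± 0.16), Bmf (-2.70 ± 0.09) and Sik1 (-2.46 ± 0.13) stood out. Txnip (-4.38 ± 0.13), which overlaps another annotated gene, fell as well. Secondary inflammatory genes, which need new protein or chromatin changes for their induction, counted 16 risen and 0 fallen of 21. The median of all tested genes moved by -0.33, so the 863 genes higher and 6309 lower became 2053 and 2206 after median scaling, and 12% higher became 48.2%.

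In experiment 1, at 1 hr of lipid A, Tnf (7.93 ± 0.12, 3688 ± 378 against 14.2 ± 2.45 TPM), Cxcl2 (8.71 ± 0.10), Cxcl1 (8.40 ± 0.12) and Ptgs2 (7.54 ± 0.10) had risen. So had Il1a (9.36 ± 0.12) and Il1b (8.99 ± 0.16), which overlap antisense or predicted genes and are less certain because reads were counted on both strands. All 24 measured immediate early genes and all 30 primary NF-kB genes rose, together with 19 of 24 secondary genes. Interferon response genes were mixed (16 rose and 4 fell of 39).
At 4 hr the large increases included Ptgs2 (9.32 ± 0.13), the nitric oxide synthase gene Nos2 (8.75 ± 0.18), Il6 (8.47 ± 0.18) and the itaconate synthase gene Acod1 (8.46 ± 0.16). Sesn1 (-6.66 ± 0.18) and Cxcr4 (-6.35 ± 0.20) were among the largest decreases. By then 36 of 39 interferon response genes, 21 of 24 secondary genes and 27 of 30 primary genes had risen and none of these had fallen. In contrast 9 of 15 LXR targets, 14 of 23 cell cycle genes and 12 of 18 p53 targets had fallen. Ifnb1 was lower at 4 hr (10.5 TPM) than at 1 hr (456 TPM) of lipid A. Medians of all genes moved by -0.38 at 1 hr and -0.84 at 4 hr. The counts of 1142 higher and 6123 lower at 1 hr became 2229 and 2577 after median scaling (15.7% and 46.4% higher). At 4 hr, 2319 and 7062 became 3756 and 4979 (24.7% and 43% higher). The authors' deposited table calls 1733 higher and 1215 lower at 1 hr, and 4232 and 3674 at 4 hr.

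The LPS control series of experiment 2, in Arid1a f/f cells, gave the chemokine genes Ccl2 (10.46 ± 0.44) and Ccl7 (9.76 ± 0.57) and Tnf (8.66 ± 0.55) as large increases at 1 hr. Nos2 (0.07 ± 0.11, adjusted p = 0.642) lay near the floor. All 30 primary NF-kB genes, 22 of 23 immediate early genes and 17 of 22 secondary genes rose at 1 hr, and 17 of 25 cell cycle genes rose.
At 4 hr Ccl5 (10.88 ± 0.33), Acod1 (10.52 ± 0.33), Nos2 (9.33 ± 0.11) and Il6 (9.06 ± 0.11) were among the largest increases. The chemokine receptor gene Cxcr4 (-7.24 ± 0.13) and the iron exporter gene Slc40a1 (-6.02 ± 0.09) fell. All 39 interferon response genes and all 22 secondary genes rose, and 13 of 24 cholesterol synthesis genes rose and 4 fell. Of 25 cell cycle genes 20 fell and 2 rose. Counts were 1612 higher and 3634 lower at 1 hr (2064 and 2554 after median scaling, 30.7% and 44.7% higher). At 4 hr they were 2115 and 7407 (3644 and 4603, 22.2% and 44.2% higher). The all-gene medians were -0.15 and -0.63. Without 0 hr control replicate 2 the total at 1 hr was 3460.
In Pbrm1 f/f control cells of experiment 3, 4 hr of lipid A raised Acod1 (9.02 ± 0.14), Nos2 (8.11 ± 0.79), Cxcl9 (7.67 ± 0.62), Cd69 (7.55 ± 0.29) and Ptgs2 (7.24 ± 0.64) and lowered Slc40a1 (-5.74 ± 0.29) and Cxcr4 (-5.51 ± 0.24). There 28 of 29 primary, 19 of 21 secondary and 37 of 39 interferon response genes rose. The 1774 genes higher and 6838 lower became 3024 and 4083 after median scaling (20.6% and 42.5% higher), with an all-gene median of -0.75. Across genes, which are not independent replicates, 4 hr responses correlated at r = 0.93 between experiments 1 and 3, 0.91 between 2 and 3 and 0.86 between 1 and 2, and the 1 hr responses of 1 and 4 at 0.86.

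ACBI1 lowered Mmp13, Saa3 and Il6 in cells given lipid A for 4 hr, and raised Ifnb1, Tnf and Hmox1. The targeted ATPase genes did not fall together. Smarca4 (0.83 ± 0.11, adjusted p = 0.000236, 81.8 ± 10.2 against 45.5 TPM) rose. Smarca2 (-0.40 ± 0.17, adjusted p = 0.0785), which overlaps an annotated RNA, Pbrm1 (0.01 ± 0.14, adjusted p = 0.955) and Arid1a (0.53 ± 0.11, adjusted p = 0.00291) did not pass on both scalings. After median scaling Smarca2 was -0.68 (adjusted p = 0.0066), and with voom on recovered reads Pbrm1 was -0.35 (adjusted p = 0.0305). Transcript levels say nothing of the protein that a degrader acts on. The collagenase gene Mmp13 (-5.87 ± 0.17, 57.2 ± 4.35 against 3394 TPM), the lipase gene Lipg (-4.51 ± 0.20), the acute phase gene Saa3 (-2.84 ± 0.47), the transcription factor gene Maf (-2.97 ± 0.14, 75.6 ± 6.44 against 598 TPM) and the chemokine gene Cxcl9 (-2.94 ± 0.40) fell. Gdf15 (4.73 ± 0.25), Htra4 (3.65 ± 0.18), Lhfpl2 (3.87 ± 0.14) and Apol7c (3.84 ± 0.22) rose. Of the reference cytokines, Tnf (1.69 ± 0.14, 3136 ± 148 against 968 TPM) and Ifnb1 (4.07 ± 0.30, 196 ± 48.6 against 10.5 TPM) rose. Il6 (-1.58 ± 0.18, 138 ± 24.5 against 410.0 TPM), Il10 (-2.14 ± 0.21) and Ptgs2 (-0.82 ± 0.13) fell. Il12b (0.34 ± 0.13, adjusted p = 0.0491) and Nos2 (0.18 ± 0.18, adjusted p = 0.461) did not pass on both scalings.

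Of 24 measured secondary inflammatory genes 3 rose, 13 fell and 8 did not pass (3 and 14 adjusted over the list alone, camera adjusted p = 3.65e-05, or 0.198 with an estimated correlation). Cp (-2.43 ± 0.22) and Hdc (-2.40 ± 0.18) fell. Primary NF-kB genes split, Tnfaip2 (2.07 ± 0.10) and Cxcl1 (1.82 ± 0.15) rising and Ccl7 (-1.91 ± 0.22) falling. Of the 30 measured, 9 rose, 12 fell and 9 did not pass (10 and 12 adjusted over the list alone, camera adjusted p = 0.443). Among cholesterol synthesis genes Mvd (2.54 ± 0.22) and Ebp (1.01 ± 0.12) rose. Of the 24 measured, 14 rose, 0 fell and 10 did not pass (camera adjusted p = 0.0137, or 0.198 with an estimated correlation). Among NRF2 targets Srxn1 (4.04 ± 0.14), Osgin1 (3.59 ± 0.25) and the heme oxygenase gene Hmox1 (3.39 ± 0.09, 1135 ± 62 against 108 TPM) rose. Osgin1 held 0.092 TPM in the control, near the floor, so the size of its change depends on the 1 added to TPM (6.10 with voom). Of the 14 measured, 9 rose, 1 fell and 4 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 0.00351, or 0.227 with an estimated correlation). Of 14 inflammasome genes 1 rose, 5 fell and 8 did not pass (camera adjusted p = 0.0103, or 0.504 with an estimated correlation). Mefv (-1.35 ± 0.16) and Aim2 (-0.89 ± 0.19) fell. Of 25 macrophage identity genes 3 rose, 7 fell and 15 did not pass (camera adjusted p = 0.0103, or 0.165 with an estimated correlation). Axl (-1.58 ± 0.18) and Fcgr3 (-1.32 ± 0.09) fell. SWI/SNF subunit genes included Smarcd1 (1.06 ± 0.16), Smarcb1 (1.04 ± 0.16) and Arid2 (1.03 ± 0.11) among the increases. Of the 25 measured, 8 rose, 1 fell and 16 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.58).

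Elsewhere, risen and fallen members were 2 and 6 of 24 immediate early genes, 6 and 5 of 39 interferon response genes and 6 and 10 of 28 TLR4 signalling genes. They were 7 and 1 of 23 cell cycle genes (Ccne1 (3.12 ± 0.48), Cdt1 (3.08 ± 0.18), Pcna (1.78 ± 0.10)) and 7 and 2 of 18 p53 targets (Phlda3 (1.65 ± 0.25)). They were 3 and 1 of 15 LXR targets, 4 and 2 of 13 alternative activation genes, 5 and 4 of 22 glycolysis and hypoxia genes, 5 and 2 of 19 stress response genes and 3 and 1 of 14 heat shock genes. Markers of other cell types gave 0 and 0 of 8 granulocyte, 0 and 1 of 8 dendritic cell, 1 and 0 of 3 lymphocyte and 0 and 1 of 2 stromal markers. Of 14 erythroid and mast cell markers 0 were measured in any experiment. Of 1066 genes induced by lipid A in experiment 3, 115 rose and 445 fell with ACBI1 (median -0.26 against 0.28 for other genes; adjusted p = 3.48e-15, adjusted p = 0.164 with an estimated correlation). ACBI1 moved 3983 genes higher and 1552 lower, 2585 and 2712 after median scaling (72% and 48.8% higher), around an all-gene median of 0.25. The authors' deposited table, which names 1 control library in duplicate, calls 2094 higher and 2803 lower. With a single control library at 4 hr, the error comes from the other groups of the experiment.

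BRM014 at 4 hr removed most of the induced level of Saa3, Mmp13 and Nos2 and raised Ifnb1 further than ACBI1 did. Saa3 (-7.44 ± 0.47, 46.9 ± 8.13 against 8254 TPM), Mmp13 (-7.04 ± 0.17), the formyl peptide receptor genes Fpr2 (-6.17 ± 0.34) and Fpr1 (-5.82 ± 0.23), the endothelin gene Edn1 (-5.91 ± 0.20) and Nos2 (-5.72 ± 0.18, 8.53 ± 1.1 against 501 TPM) fell. So did Il12b (-3.52 ± 0.13), Ptgs2 (-3.13 ± 0.13), Il10 (-2.34 ± 0.21), Ccl5 (-1.68 ± 0.11), Il6 (-1.63 ± 0.18) and Il1b (-1.40 ± 0.19). Ifnb1 (6.50 ± 0.30, 1039 ± 48.4 against 10.5 TPM) and Tnf (1.07 ± 0.14) rose. Srxn1 (5.33 ± 0.14), Rassf5 (4.62 ± 0.13) and the RNA polymerase II subunit gene Polr2g (4.33 ± 0.12) were among the largest increases. Il23a (4.26 ± 0.20, 18.3 ± 3.87 against 0 TPM) rose from a listed 0, so its size depends on the 1 added to TPM. Smarca4 (0.57 ± 0.11, adjusted p = 0.00127), Smarca2 (0.19 ± 0.17, adjusted p = 0.368) and Pbrm1 (0.45 ± 0.14, adjusted p = 0.0137) did not pass on both scalings, and Arid1a (-0.38 ± 0.11, adjusted p = 0.0125) fell.

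Of 24 secondary inflammatory genes 1 rose, 18 fell and 5 did not pass (camera adjusted p = 5.73e-13, or 0.0775 with an estimated correlation). Among primary NF-kB genes Ccl7 (-4.88 ± 0.22) and Traf1 (-2.38 ± 0.17) fell. Of the 30 measured, 6 rose, 12 fell and 12 did not pass (7 and 12 adjusted over the list alone, camera adjusted p = 0.00584, or 0.401 with an estimated correlation). Of 25 macrophage identity genes 1 rose, 12 fell and 12 did not pass (camera adjusted p = 0.000344, or 0.0775 with an estimated correlation). Maf (-4.31 ± 0.14), Axl (-3.11 ± 0.18), Fcgr3 (-2.48 ± 0.09) and Mertk (-2.16 ± 0.10) fell. Inflammasome genes Mefv (-2.90 ± 0.16), Aim2 (-1.86 ± 0.19) and the adaptor gene Pycard (-1.65 ± 0.11) fell. Of the 14 measured, 2 rose, 7 fell and 5 did not pass (camera adjusted p = 0.00289, or 0.41 with an estimated correlation). Among cell cycle genes Cdt1 (3.35 ± 0.18), Pcna (2.99 ± 0.10) and Ccne1 (2.59 ± 0.48) rose. Of the 23 measured, 10 rose, 0 fell and 13 did not pass (camera adjusted p = 0.0357, or 0.573 with an estimated correlation). NRF2 targets included Hmox1 (2.73 ± 0.09) and Gclc (2.67 ± 0.19), with 8 and 2 of 14 risen and fallen and a camera adjusted p = 0.177. Other counts of risen and fallen members were 9 and 6 of 24 immediate early, 6 and 8 of 39 interferon response (Cxcl9 (-5.03 ± 0.40) lower), and 8 and 9 of 28 TLR4 signalling genes. They were 7 and 3 of 24 cholesterol synthesis (Sqle (1.48 ± 0.11) higher), 3 and 4 of 15 LXR (Abcg1 (-2.67 ± 0.20) lower) and 1 and 4 of 13 alternative activation (Ccl24 (-3.46 ± 0.18) lower) genes. Of 2 stromal markers 0 rose, 1 fell and 1 did not pass (camera adjusted p = 0.0384, or 0.227 with an estimated correlation). The receptor gene Kdr (-3.59 ± 0.19) fell.

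Of 1066 genes induced by lipid A in experiment 3, 87 rose and 637 fell (median -0.68 against 0.50 for other genes; adjusted p = 2e-36, adjusted p = 0.085 with an estimated correlation). BRM014 moved 5570 genes higher and 1889 lower, 3382 and 3201 after median scaling (74.7% and 51.4% higher), around an all-gene median of 0.43. In the authors' deposited table these were 2535 and 3358.

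BRDK98 at 4 hr lowered Saa3, Nos2 and the macrophage regulator genes Cebpb, Maf and Spi1, and raised Ifnb1. Saa3 (-8.05 ± 0.47, 30.2 ± 2.56 against 8254 TPM), Edn1 (-6.31 ± 0.20), the matrix protease gene Mmp14 (-5.46 ± 0.33), the iron-binding lipocalin gene Lcn2 (-5.36 ± 0.26), the prostaglandin synthase gene Ptges (-4.90 ± 0.16) and Slamf1 (-5.01 ± 0.18) fell. Pou2f2 (-6.41 ± 0.13) and Il4i1 (-5.02 ± 0.16) fell too, both of which overlap other annotated genes. Il12b (-1.49 ± 0.13), Nos2 (-3.16 ± 0.18), Ptgs2 (-2.23 ± 0.13), Il10 (-2.45 ± 0.21) and Ccl5 (-0.84 ± 0.11) and Il1b (-3.81 ± 0.19) fell and Ifnb1 (3.77 ± 0.30) rose. Tnf (0.34 ± 0.14, adjusted p = 0.0652) and Il6 (0.12 ± 0.18, adjusted p = 0.594) did not pass, though with voom on recovered reads Il6 was -0.53 (adjusted p = 0.00684). Ncapg2 (3.43 ± 0.14), the tissue factor gene F3 (3.39 ± 0.18), Mknk2 (3.26 ± 0.15) and Sesn3 (3.21 ± 0.14) were among the largest increases. Arid1a (-1.03 ± 0.11, 23.2 ± 0.935 against 48.3 TPM) fell. Smarca4 (0.79 ± 0.11, adjusted p = 0.000186), Smarca2 (0.17 ± 0.17, adjusted p = 0.407) and Pbrm1 (0.01 ± 0.14, adjusted p = 0.937) did not pass on both scalings. Pbrm1 turned lower on scaled TPM (-0.53, adjusted p = 0.00525) and with voom (-0.63, adjusted p = 0.00035).

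Of 24 cholesterol synthesis genes 3 rose, 15 fell and 6 did not pass (camera adjusted p = 2.77e-08, or 0.0501 with an estimated correlation). Cyp51 (-2.95 ± 0.12), Hmgcs1 (-2.77 ± 0.10), Msmo1 (-1.97 ± 0.10) and Fdps (-1.96 ± 0.15) fell. Of 25 macrophage identity genes 1 rose, 13 fell and 11 did not pass (camera adjusted p = 3.09e-07, or 0.0501 with an estimated correlation). The lineage regulator genes Cebpb (-3.57 ± 0.44), Maf (-3.36 ± 0.14) and Spi1 (-2.68 ± 0.15) fell. Of 24 secondary genes 0 rose, 18 fell and 6 did not pass (0 and 19 adjusted over the list alone, camera adjusted p = 8.95e-17, or 0.0569 with an estimated correlation). Of 30 primary genes 2 rose, 13 fell and 15 did not pass (camera adjusted p = 2.51e-05, or 0.227 with an estimated correlation). Traf1 (-3.81 ± 0.17), Bcl3 (-3.43 ± 0.23) and Sod2 (-3.03 ± 0.09) fell. Among immediate early genes Dusp1 (-4.86 ± 0.16), Ier2 (-3.23 ± 0.26), Ier3 (-2.49 ± 0.16) and Zfp36 (-2.05 ± 0.12) fell. Of the 24 measured, 2 rose, 12 fell and 10 did not pass (camera adjusted p = 1.7e-07, or 0.165 with an estimated correlation). Of 13 alternative activation genes 1 rose, 6 fell and 6 did not pass (camera adjusted p = 0.000477, or 0.0878 with an estimated correlation). Il4ra (-4.19 ± 0.14) and Ccl24 (-3.87 ± 0.18) fell. Of 14 NRF2 targets 1 rose, 6 fell and 7 did not pass (camera adjusted p = 0.0031, or 0.227 with an estimated correlation). Gsr (-2.72 ± 0.10) fell. Of 14 inflammasome genes 0 rose, 4 fell and 10 did not pass (camera adjusted p = 0.00155, or 0.408 with an estimated correlation). Nlrp3 (-2.76 ± 0.09) fell. Of 22 glycolysis and hypoxia genes 1 rose, 5 fell and 16 did not pass (camera adjusted p = 0.0111, or 0.393 with an estimated correlation). Pfkfb3 (-2.70 ± 0.15) fell. The granulocyte markers Csf3r (-2.84 ± 0.13), S100a9 (-1.75 ± 0.28) and S100a8 (-1.49 ± 0.37) fell. Of the 8 measured, 0 rose, 4 fell and 4 did not pass (camera adjusted p = 0.00154, or 0.291 with an estimated correlation). Of 8 dendritic cell markers 0 rose, 2 fell and 6 did not pass (camera adjusted p = 0.0153, or 0.198 with an estimated correlation). H2-Ab1 (-1.45 ± 0.10) fell.

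Of 1066 genes induced by lipid A in experiment 3, 65 rose and 479 fell (median -0.28 against 0.51; adjusted p = 7.95e-27, adjusted p = 0.1 with an estimated correlation). Counts were 5717 higher and 1435 lower, 2852 and 3154 after median scaling (79.9% and 47.5% higher), around an all-gene median of 0.46. The authors' deposited table has 2386 and 3370.

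**Figure D1:**
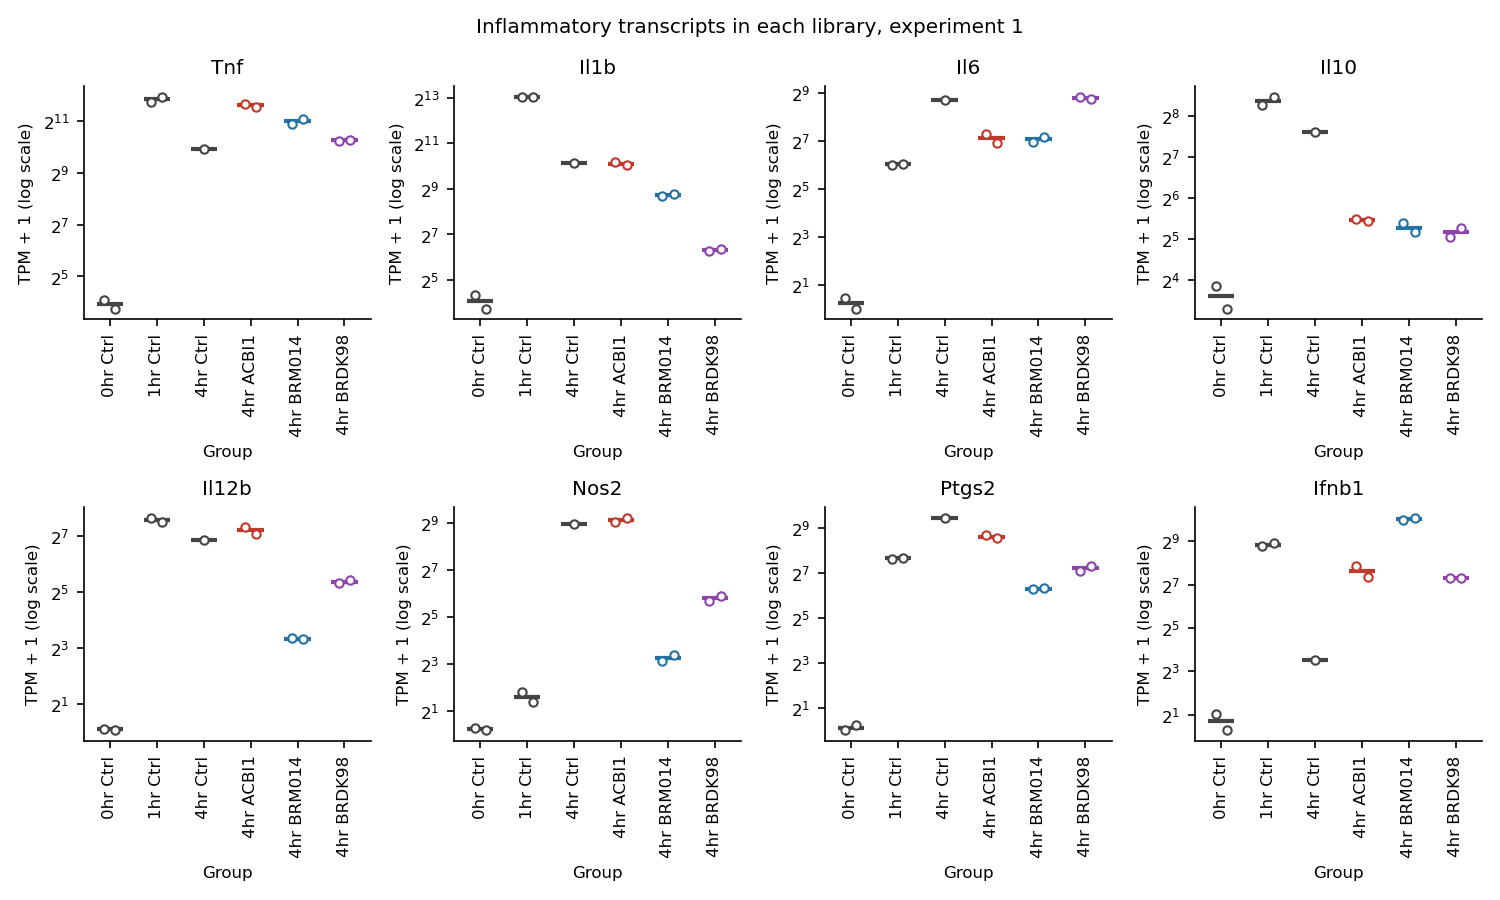
Level of 8 inflammatory transcripts in each library of experiment 1 (y axis, TPM plus 1, log scale; x axis, group; circles, libraries; bars, group means; the 4 hr control has 1 library). Nos2 with BRM014 averages 8.53 TPM against 501 TPM in the control, and Ifnb1 averages 1039 TPM against 10.5 TPM.

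Tested directly against each other at 4 hr, with 2 libraries each, the compounds differed in several cytokine genes. BRM014 gave less Nos2 (-5.90 ± 0.15), Il12b (-3.87 ± 0.10), Ptgs2 (-2.31 ± 0.10), Ccl5 (-1.83 ± 0.09) and Tnf (-0.63 ± 0.12) and more Ifnb1 (2.42 ± 0.24) and the alarmin gene Il33 (3.82 ± 0.20) than ACBI1. It also gave less of the scavenger receptor gene Marco (-4.82 ± 0.09) and the coagulation factor gene F10 (-5.37 ± 0.12). Il6 (-0.04, 95% interval -0.38 to 0.29, adjusted p = 0.837) and Il10 (-0.20, 95% interval -0.58 to 0.19, adjusted p = 0.377) did not pass, though Il10 did with voom (-0.42, adjusted p = 0.0314).
BRDK98 gave less Nos2 (-3.34 ± 0.15), Il12b (-1.83 ± 0.10), Tnf (-1.36 ± 0.12), Marco (-6.35 ± 0.09) and Saa3 (-5.21 ± 0.38) than ACBI1. It gave more Il6 (1.70 ± 0.15), Ncapg2 (3.83 ± 0.12) and Hap1 (3.92 ± 0.18). Ifnb1 (-0.31, 95% interval -0.87 to 0.26, adjusted p = 0.33) and Il10 (-0.31, 95% interval -0.69 to 0.07, adjusted p = 0.157) did not pass on both scalings, though both did with voom (-0.59 and -0.60, adjusted p = 0.00393 and 0.00203).
Against BRM014, BRDK98 gave more Nos2 (2.56 ± 0.15), Il12b (2.04 ± 0.10), Il6 (1.75 ± 0.15), Cd69 (6.38 ± 0.15) and Ifit1bl1 (6.28 ± 0.33). It gave less Ifnb1 (-2.73 ± 0.24), Tnf (-0.73 ± 0.12), Srxn1 (-4.60 ± 0.12) and the receptor genes Adora2b (-5.45 ± 0.10) and Gpr84 (-4.59 ± 0.12). Counts higher and lower were 3528 and 1627 for BRM014 against ACBI1 (2013 and 2230 after median scaling, 68.4% and 47.4% higher). They were 4296 and 1771 for BRDK98 against ACBI1 (2496 and 2740, 70.8% and 47.7% higher). BRDK98 against BRM014 gave 2965 and 2544 (2615 and 3008, 53.8% and 46.5% higher). All-gene medians against ACBI1 were 0.18 and 0.21.

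The responses to the 3 compounds shared one control library, which alone makes them resemble each other. Across genes, which are not independent replicates, r was 0.76 for ACBI1 and BRM014, 0.53 for ACBI1 and BRDK98 and 0.64 for BRM014 and BRDK98. Unchanged groups simulated with the same shared control gave 0.67. The covariances were 0.517, 0.31 and 0.528 against 0.039 in the simulation. Genes higher with both compounds numbered 2001, 1518 and 1878 where 754.7, 636.4 and 836.5 would fall together by number alone. Genes lower with both numbered 1146, 704 and 915 where 254.2, 193.1 and 235.1 would. The shared control adds to these overlaps by an amount that cannot be separated with 1 library.

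Loss of Arid1a, which encodes a DNA-binding subunit of SWI/SNF, was followed in LPS-stimulated cells by lower Il12b, Il10, Il6 and LXR target transcripts and higher cell cycle transcripts at 1 hr. Arid1a itself (NM_001363070, chromosome 4, 133679008 to 133756769, mm10) fell by 0.80 ± 0.21 on the log2 scale (adjusted p = 0.0165; 10.2 ± 4.25 against 17.8 ± 0.696 TPM), and a microRNA gene overlaps it. The knockout libraries held 7.17 and 13.2 TPM, so transcript remained in each. Values per gene cannot show whether the floxed exons were lost. Il12b (-3.24 ± 0.11, 2.67 ± 0.489 against 33.6 ± 1.76 TPM), Il10 (-2.90 ± 0.26), Ccl5 (-2.20 ± 0.33), Il6 (-1.45 ± 0.11) and Il1b (-3.37 ± 0.16) fell. Ifnb1 (-0.23 ± 0.19, adjusted p = 0.364) and Ptgs2 (-0.07 ± 0.17, adjusted p = 0.772) did not pass. Nor did Tnf (1.20 ± 0.55, adjusted p = 0.144, 4994 ± 270.0 against 2178 ± 79.2 TPM), except with voom (adjusted p = 0.00755). Its error, here and at 4 hr, is pooled with the 0 hr controls (9.28 and 1.81 TPM). The lipid exporter gene Abca1 (-3.44 ± 0.29) and Ms4a4a (-4.54 ± 0.14) were among the largest decreases. Etv5 (2.70 ± 0.14), Nptx1 (3.08 ± 0.18), Srm (2.67 ± 0.18) and Nes (2.21 ± 0.12) were among the largest increases. Ccnd1 (4.20 ± 0.11) and its overlapping neighbour rose together and cannot be assigned singly.

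Among primary NF-kB genes Bcl3 (-2.38 ± 0.14) and Cd40 (-1.87 ± 0.24) fell. Of the 30 measured, 1 rose, 16 fell and 13 did not pass (2 and 16 adjusted over the list alone, camera adjusted p = 1.18e-05, or 0.416 with an estimated correlation). Of 22 secondary genes 0 rose, 14 fell and 8 did not pass (camera adjusted p = 8.45e-05, or 0.204 with an estimated correlation). Csf2 (-2.09 ± 0.17) and Ccl22 (-2.08 ± 0.16) fell. Among interferon response genes Usp18 (2.34 ± 0.14) and Ifit3 (1.85 ± 0.12) rose and Gbp5 (-2.15 ± 0.09) fell. Of the 39 measured, 22 rose, 6 fell and 11 did not pass (22 and 7 adjusted over the list alone, camera adjusted p = 0.00108, or 0.465 with an estimated correlation). Among LXR targets Abcg1 (-2.16 ± 0.10) and Abca9 (-1.76 ± 0.18) fell. Of the 15 measured, 0 rose, 11 fell and 4 did not pass (0 and 13 adjusted over the list alone, camera adjusted p = 2.55e-07, or 0.0448 with an estimated correlation). Among cell cycle genes Ccne1 (1.84 ± 0.17), Mcm2 (1.80 ± 0.13) and Mcm3 (1.59 ± 0.10) rose. Of the 25 measured, 14 rose, 0 fell and 11 did not pass (camera adjusted p = 3.61e-07, or 0.0448 with an estimated correlation). Among genes of the unfolded protein and integrated stress responses Chac1 (2.46 ± 0.33), Trib3 (1.93 ± 0.22) and Asns (1.77 ± 0.14) rose. Of the 22 measured, 16 rose, 2 fell and 4 did not pass (camera adjusted p = 2.38e-05, or 0.204 with an estimated correlation). Of 22 glycolysis and hypoxia genes 16 rose, 3 fell and 3 did not pass (camera adjusted p = 0.000479, or 0.204 with an estimated correlation). Ldha (1.02 ± 0.07) rose. Of 28 TLR4 signalling genes 0 rose, 13 fell and 15 did not pass (camera adjusted p = 0.000252, or 0.326 with an estimated correlation). Ticam2 (-1.63 ± 0.10) and Irak2 (-1.32 ± 0.11) fell. Of 14 inflammasome genes 0 rose, 9 fell and 5 did not pass (camera adjusted p = 0.000521, or 0.204 with an estimated correlation). Casp4 (-1.28 ± 0.11) and Nlrp3 (-1.12 ± 0.09) fell.

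Of 25 macrophage identity genes 2 rose, 14 fell and 9 did not pass (camera adjusted p = 0.000559, or 0.224 with an estimated correlation). C1qc (-1.20 ± 0.11) fell and Cx3cr1 (1.23 ± 0.14) rose. Immediate early genes split between Egr3 (-2.43 ± 0.13) and Fos (1.04 ± 0.31). Of the 23 measured, 4 rose, 8 fell and 11 did not pass (4 and 9 adjusted over the list alone, camera adjusted p = 0.0481, or 0.644 with an estimated correlation). Of 15 NRF2 targets 6 rose, 2 fell and 7 did not pass (camera adjusted p = 0.0384, or 0.242 with an estimated correlation). Of 15 alternative activation genes 3 rose, 7 fell and 5 did not pass (3 and 8 adjusted over the list alone, camera adjusted p = 0.0136, or 0.326 with an estimated correlation). Clec10a (-1.53 ± 0.20) fell. Of the 541 genes that lipid A raised at 1 hr in experiment 1, 40 rose and 317 fell (median -0.55 against 0.04; adjusted p = 2.32e-19, adjusted p = 0.1 with an estimated correlation). Counts were 2644 higher and 1990 lower, 2171 and 2338 after median scaling. The authors' deposited table gives 1358 and 1316. Leaving out a library moved the total from 2763 (without 1 hr control replicate 2) to 5414 (without knockout replicate 2).

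After 4 hr of LPS the Arid1a knockout cells held less cholesterol synthesis and LXR target transcript and more cell cycle transcript. Arid1a (-0.56 ± 0.21, adjusted p = 0.0838; 25.7 ± 0.473 against 38.5 ± 4.72 TPM) did not pass at this time on TPM as deposited, and had an adjusted p = 0.0311 after median scaling. Ifnb1 (3.09 ± 0.19, 46.3 ± 2.66 against 4.62 ± 1.24 TPM), the urokinase gene Plau (3.07 ± 0.32), the arginase gene Arg1 (2.89 ± 0.22), Sgk1 (2.04 ± 0.13) and Mmp12 (2.02 ± 0.12) rose. Ccl24 (-2.95 ± 0.19), Tmem176a (-2.74 ± 0.16), Dusp1 (-2.60 ± 0.33), the metallothionein gene Mt2 (-2.46 ± 0.11) and Cp (-2.42 ± 0.16) fell. Of the reference genes Il6 (0.65 ± 0.11), Il12b (0.52 ± 0.11) and Nos2 (0.73 ± 0.11) were higher and Il10 (-0.90 ± 0.26) and Il1b (-1.79 ± 0.16) lower. Ptgs2 (0.14 ± 0.17, adjusted p = 0.572), Ccl5 (-0.51 ± 0.33, adjusted p = 0.313) and Tnf (0.99 ± 0.55, adjusted p = 0.25) did not pass, though the last 2 did with voom (adjusted p = 0.00439 and 0.0324).

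Of 24 cholesterol synthesis genes 2 rose, 20 fell and 2 did not pass (camera adjusted p = 5.1e-11, or 0.0448 with an estimated correlation). Sc5d (-1.89 ± 0.11), Cyp51 (-1.71 ± 0.10), Hmgcs1 (-1.70 ± 0.11) and Msmo1 (-1.58 ± 0.10) fell. Of 15 LXR targets 1 rose, 11 fell and 3 did not pass (camera adjusted p = 2.41e-06, or 0.0448 with an estimated correlation). Abca1 (-1.76 ± 0.29) and Apoe (-1.32 ± 0.09) fell. Among cell cycle genes Rrm2 (1.95 ± 0.12), Mcm2 (1.87 ± 0.13) and Mcm5 (1.60 ± 0.11) rose. Of the 25 measured, 18 rose, 0 fell and 7 did not pass (20 and 0 adjusted over the list alone, camera adjusted p = 5.1e-11, or 0.0448 with an estimated correlation). The immediate early genes Ier2 (-2.17 ± 0.14) and Dusp2 (-1.24 ± 0.15) fell. Of the 23 measured, 1 rose, 9 fell and 13 did not pass (camera adjusted p = 0.000521, or 0.416 with an estimated correlation). Of 22 secondary genes 6 rose, 11 fell and 5 did not pass (camera adjusted p = 0.0398, or 0.416 with an estimated correlation). Lcn2 (-1.84 ± 0.21) and Saa3 (-1.52 ± 0.19) fell. Of 25 macrophage identity genes 1 rose, 11 fell and 13 did not pass (camera adjusted p = 0.00504, or 0.297 with an estimated correlation). Cebpb (-1.97 ± 0.24) fell. Of 14 inflammasome genes 1 rose, 7 fell and 6 did not pass (camera adjusted p = 0.00758, or 0.265 with an estimated correlation). Of 15 NRF2 targets 8 rose, 1 fell and 6 did not pass (camera adjusted p = 0.00746, or 0.204 with an estimated correlation). Slc7a11 (1.24 ± 0.17) rose. Risen and fallen members in other lists were 5 and 6 of 30 primary NF-kB, 5 and 4 of 39 interferon response, 10 and 3 of 22 glycolysis and hypoxia, 9 and 4 of 22 stress response and 7 and 4 of 14 heat shock genes (Hspd1 (1.19 ± 0.10) higher). Their camera adjusted p were 0.226, 0.997, 0.134, 0.117 and 0.58.

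Of the 1314 genes raised by lipid A at 4 hr in experiment 1, 143 rose and 267 fell (median -0.03 against 0.06; adjusted p = 0.00221, adjusted p = 0.376 with an estimated correlation). Without 4 hr control replicate 1 this adjusted p was 0.0709. Counts were 2057 higher and 1280 lower, 1689 and 1826 after median scaling (61.6% and 48.1% higher), and the authors' deposited table has 1299 and 1432. The total was 2005 without knockout replicate 1.
The effect of Arid1a loss differed between 4 hr and 1 hr for 1982 genes, 1010 in the higher and 972 in the lower direction. Il12b (3.76 ± 0.15), Ifnb1 (3.32 ± 0.27) and Il6 (2.10 ± 0.16) moved toward higher levels with time, as did the activation marker gene Cd69 (2.84 ± 0.16). Nek6 (-2.65 ± 0.13), Pla2g4a (-2.42 ± 0.15) and Etv5 (-2.42 ± 0.20) moved toward lower levels. Called at both times in opposite directions were 161 genes, 74 higher and then lower and 87 lower and then higher, the latter including Il6 and Il12b. The number of genes whose effect differed ranged from 961 (without 1 hr control replicate 2) to 3424 (without 1 hr knockout replicate 2).

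Few transcripts passed the test for loss of Pbrm1, which encodes the bromodomain subunit of the PBAF form of SWI/SNF, after 4 hr of lipid A. Pbrm1 (NM_001081251, chromosome 14, 31019138 to 31121592, mm10) differed by -1.48 ± 0.17 on the log2 scale (adjusted p = 0.0265; 4.79 ± 0.344 against 15.2 ± 0.663 TPM) and was lower in each knockout library than in each control library. After median scaling its adjusted p was 0.104. The lectin gene Mgl2 (-1.65 ± 0.19, adjusted p = 0.0265) and the glutathione peroxidase gene Gpx3 (-1.47 ± 0.17, adjusted p = 0.0292) were also lower on TPM as deposited, as was Mir1668 (-2.23 ± 0.26, adjusted p = 0.034), which lies inside another gene. The reference genes Tnf (-0.02 ± 0.14, adjusted p = 0.971), Il6 (0.84 ± 0.70, adjusted p = 0.676), Nos2 (1.04 ± 0.79, adjusted p = 0.646), Il10 (1.19 ± 0.75, adjusted p = 0.593) and Ptgs2 (1.19 ± 0.64, adjusted p = 0.548) did not pass.

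No list member passed both scalings, and the shifts of whole lists go with a difference between the control libraries. At 4 hr control replicates 1 and 2 held 231 and 58.5 TPM of Il6, 628 and 128 of Nos2 and 325 and 90.2 of Ptgs2. The median was 0.41 relative to all genes for 29 primary NF-kB genes (camera adjusted p = 6.47e-10) and 0.54 for 21 secondary genes (camera adjusted p = 1.48e-08). It was 0.24 for 39 interferon response genes (camera adjusted p = 6.59e-07). All 3 lost the call, with adjusted p = 0.651 with an estimated correlation. For 20 immediate early genes it was 0.26 (camera adjusted p = 1.03e-06, adjusted p = 0.227 with an estimated correlation). Lower medians came from 23 cholesterol synthesis genes (-0.38, camera adjusted p = 0.000145) and 9 granulocyte markers (-0.42, camera adjusted p = 0.000994). Both lost the call, with adjusted p = 0.651 with an estimated correlation, and 5 granulocyte markers were lower when adjusted over the list alone. Of the 1349 genes that lipid A raised at 4 hr in experiment 1, 0 passed in either direction (median 0.09 against -0.14; adjusted p = 2.64e-21, adjusted p = 0.164 with an estimated correlation). This adjusted p was 9.55e-33 without control replicate 1 and 0.0122 without control replicate 2.

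With limma on TPM as deposited, 0 genes were higher and 7 lower, around an all-gene median of -0.12. By count, 1 gene passed after median scaling and 2 with voom on recovered reads. Genes at unadjusted p below 0.05 numbered 1148, 954 and 929, and the authors' deposited table calls 1 higher and 10 lower. The count rests on the 4 hr control libraries, whose difference had an SD of 0.444, the largest of any group. It was 2178 without control replicate 1, 12 without control replicate 2 and 0 without knockout replicate 2.

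At 20 min of lipid A, ACBI1 raised a few primary NF-kB transcripts and lowered a few immediate early ones. Il1b (1.04 ± 0.13), Cd83 (0.70 ± 0.09), Cxcl2 (0.64 ± 0.08), the NF-kB inhibitor gene Tnfaip3 (0.55 ± 0.08) and Maff (0.91 ± 0.10) rose. Jun (-0.83 ± 0.12), Ier5 (-0.62 ± 0.08), Klf2 (-0.61 ± 0.09) and Nr4a1 (-0.59 ± 0.10) fell, with Actb (-0.52 ± 0.06). Tnf (0.30 ± 0.08, adjusted p = 0.409), Smarca4 (-0.15 ± 0.11, adjusted p = 0.897) and Pbrm1 (-0.22 ± 0.22, adjusted p = 0.898) did not pass. Of 30 primary NF-kB genes 4 rose, 0 fell and 26 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 6.82e-16, or 0.00979 with an estimated correlation). Of 23 immediate early genes 1 rose, 4 fell and 18 did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.235). Of 39 interferon response genes 0 rose, 0 fell and 39 did not pass (camera adjusted p = 4.52e-06, or 0.722 with an estimated correlation), with a median of -0.26 relative to all genes. Of the 531 genes lipid A raised at 1 hr in experiment 1, 7 rose and 1 fell (adjusted p = 0.00117, adjusted p = 0.28 with an estimated correlation). Without ACBI1 replicate 1 this adjusted p was 0.0518. Counts were 14 higher and 9 lower (12 and 8 after median scaling), and 107 and 260 in the authors' deposited table. The total was smaller without any single library, and equally lowest without 20 min control replicate 2 and without ACBI1 replicate 1.

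BRM014 at 20 min lowered early chemokine and cytokine transcripts, Cxcl1 and Tnf among them. Cxcl1 (-2.11 ± 0.17), Tnf (-1.81 ± 0.08, 44.6 ± 0.511 against 159 ± 1.74 TPM), Il10 (-1.71 ± 0.21), Ptgs2 (-1.06 ± 0.20), the phosphatase gene Dusp2 (-1.51 ± 0.10) and the cytokine signalling inhibitor gene Socs3 (-1.19 ± 0.08) fell, with Ccrl2 (-1.40 ± 0.14), Btg2 (-1.27 ± 0.11) and Egr1 (-0.95 ± 0.15). The metallothionein gene Mt2 (1.08 ± 0.15), Rgs2 (0.69 ± 0.09) and Cenpa (0.75 ± 0.14) rose. Il6 (-0.28 ± 0.14, adjusted p = 0.569) and Ifnb1 (-0.37 ± 0.15, adjusted p = 0.494), near the floor, did not pass, nor did Smarca4 (-0.22 ± 0.11, adjusted p = 0.59) or Pbrm1 (-0.28 ± 0.22, adjusted p = 0.677). Of 30 primary genes 0 rose, 9 fell and 21 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 1.04e-12, or 0.0173 with an estimated correlation). Of 23 immediate early genes 0 rose, 7 fell and 16 did not pass (2 and 9 adjusted over the list alone, camera adjusted p = 6.67e-05, or 0.415 with an estimated correlation). Of 21 secondary genes 0 rose, 2 fell and 19 did not pass (camera adjusted p = 0.00424, or 0.302 with an estimated correlation). Of 531 induced genes 1 rose and 27 fell (adjusted p = 6.85e-07, adjusted p = 0.143 with an estimated correlation). Counts were 11 higher and 43 lower (8 and 42 after median scaling), and 231 and 481 in the authors' deposited table. Leaving out single libraries gave 22 to 24 in total, the lowest without BRM014 replicate 1.

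BRDK98 at 20 min lowered primary NF-kB and immediate early transcripts. Socs3 (-2.80 ± 0.08), Il10 (-2.43 ± 0.21), Id3 (-2.36 ± 0.11), Cxcl2 (-2.07 ± 0.08), Cxcl1 (-1.83 ± 0.17), Nr4a1 (-2.03 ± 0.10), Tnfaip3 (-1.83 ± 0.08), the oncostatin gene Osm (-1.62 ± 0.13), Tnf (-1.09 ± 0.08, 74.3 ± 10.7 against 159 ± 1.74 TPM) and Ptgs2 (-1.04 ± 0.20) fell. The histone genes Hist1h1c (0.85 ± 0.14) and H2afx (0.84 ± 0.15), Rps10 (0.71 ± 0.13) and the stress regulator gene Atf4 (0.61 ± 0.06) rose. Il6 (-0.22 ± 0.14, adjusted p = 0.587), near the floor, and Smarca4 (-0.14 ± 0.11, adjusted p = 0.674) did not pass. Of 30 primary genes 0 rose, 13 fell and 17 did not pass (0 and 18 adjusted over the list alone, camera adjusted p = 4.16e-25, or 0.00302 with an estimated correlation). Nfkbid (-1.49 ± 0.19) fell. Of 23 immediate early genes 0 rose, 13 fell and 10 did not pass (0 and 17 adjusted over the list alone, camera adjusted p = 7.89e-22, or 0.0395 with an estimated correlation). Klf6 (-1.16 ± 0.08) and Dusp1 (-1.11 ± 0.10) fell. Of 21 secondary genes 0 rose, 2 fell and 19 did not pass (camera adjusted p = 0.00142, or 0.301 with an estimated correlation). Of 531 induced genes 2 rose and 59 fell (adjusted p = 4.46e-19, adjusted p = 0.0274 with an estimated correlation). Counts were 70 higher and 103 lower (66 and 116 after median scaling), and 197 and 524 in the authors' deposited table. Leaving out single libraries gave 78 to 97 in total, the lowest without BRDK98 replicate 1.

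By 60 min ACBI1 had raised 38 of 39 interferon response genes (adjusted p = 0.301 with an estimated correlation). Ifit1bl1 (3.64 ± 0.36), Gbp4 (3.05 ± 0.24), Isg20 (2.70 ± 0.24), Tnfsf10 (2.68 ± 0.31), Iigp1 (2.61 ± 0.37) and the regulator gene Irf7 (2.30 ± 0.21) rose. Of 39 interferon response genes 38 rose, 0 fell and 1 did not pass (39 and 0 adjusted over the list alone, camera adjusted p = 6.43e-28, or 0.301 with an estimated correlation), with a median 1.58 above that of all genes. Cxcl10 (1.09 ± 0.25), Ccl5 (1.36 ± 0.15), Nos2 (1.27 ± 0.11), Il6 (0.62 ± 0.14) and Ifnb1 (0.48 ± 0.15) rose. Il12b (-1.40 ± 0.10, 14.5 ± 0.058 against 39.9 ± 2.86 TPM) and the growth factor genes Csf2 (-2.11 ± 0.12) and Vegfa (-2.62 ± 0.16) fell, as did Mex3b (-3.09 ± 0.18), Ednrb (-2.83 ± 0.11) and Gdf15 (-2.42 ± 0.16). Tnf (-0.32 ± 0.08, adjusted p = 0.00901) and Ptgs2 (0.35 ± 0.20, adjusted p = 0.183) did not pass on both scalings. Arid1a (-1.09 ± 0.26, 8.11 ± 0.0771 against 18.4 ± 1.38 TPM) fell and Smarca4 (0.36 ± 0.11) rose. Smarca2 (-0.44 ± 0.11, adjusted p = 0.00568) and Pbrm1 (-0.23 ± 0.22, adjusted p = 0.436) did not pass on both scalings.

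Of 21 secondary genes 11 rose, 4 fell and 6 did not pass (camera adjusted p = 0.0161, or 0.377 with an estimated correlation). Of 30 primary genes 5 rose, 5 fell and 20 did not pass (camera adjusted p = 0.77). Cxcl3 (-1.58 ± 0.13), Cxcl1 (-1.03 ± 0.17) and Cxcl2 (-0.88 ± 0.08) fell and Il23a (0.97 ± 0.10) rose. Of 14 inflammasome genes 9 rose, 2 fell and 3 did not pass (camera adjusted p = 0.00113, or 0.415 with an estimated correlation). Nlrp3 (-1.14 ± 0.08) fell and Gsdmd (1.03 ± 0.07) and Casp1 (0.81 ± 0.11) rose. The NRF2 targets Hmox1 (-1.10 ± 0.09) and Gclm (-0.83 ± 0.10) fell. Of the 13 measured, 0 rose, 10 fell and 3 did not pass (camera adjusted p = 0.000192, or 0.301 with an estimated correlation). Of 23 cholesterol synthesis genes 0 rose, 9 fell and 14 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 0.0165, or 0.415 with an estimated correlation). Insig1 (-0.95 ± 0.12) fell. Of 8 dendritic cell markers 4 rose, 0 fell and 4 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.00431, or 0.095 with an estimated correlation). Bst2 (1.22 ± 0.15) and Batf3 (1.06 ± 0.23) rose, of which Bst2 is itself interferon-induced. Granulocyte markers counted 1 and 5 of 12 risen and fallen (S100a9 (-0.69 ± 0.09) and S100a8 (-0.65 ± 0.11) lower). Of the 531 induced genes 112 rose and 127 fell (adjusted p = 0.697).
The effect differed between 60 and 20 min for 3112 genes, 1083 in the higher and 2029 in the lower direction (1617 and 1111 after median scaling). Ifit1bl1 (4.00 ± 0.51), Cxcl10 (1.22 ± 0.35) and Ccl5 (1.52 ± 0.21) moved higher and Vegfa (-3.00 ± 0.23) and Mex3b (-3.04 ± 0.26) lower. Il12b lay near the floor at 20 min. Opposite calls were made for 6 genes. Counts at 60 min were 1336 higher and 3203 lower, 2132 and 1671 after median scaling (29.4% and 56.1% higher), around an all-gene median of -0.14, which turns which count is larger. In the authors' deposited table there are 2008 and 1278. Without 60 min control replicate 2 the total was 2672, and 1956 genes differed between times.

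BRM014 at 60 min lowered induced cytokine transcripts, and 27 of 30 primary NF-kB genes fell. Il12b (-4.23 ± 0.10, 1.19 ± 0.193 against 39.9 ± 2.86 TPM), the repressor gene Prdm1 (-4.48 ± 0.09), Acod1 (-3.90 ± 0.18), Il10 (-3.14 ± 0.21), Il6 (-3.09 ± 0.14), Ifnb1 (-2.51 ± 0.15), Ccl5 (-1.69 ± 0.15), Cxcl10 (-1.15 ± 0.25), Ptgs2 (-0.67 ± 0.20), Tnf (-0.39 ± 0.08) and Il1b (-2.92 ± 0.13) fell. Nos2 (-0.05 ± 0.11, adjusted p = 0.744) lay near the floor. Arc (4.92 ± 0.22), Nop2 (3.92 ± 0.09), H2afx (4.12 ± 0.15), Tob1 (3.57 ± 0.22) and Fos (2.27 ± 0.13) rose. The 2 BRM014 libraries disagreed in size (Arc 72.2 ± 34.3, Tob1 135 ± 60.9 TPM), and their difference had an SD of 0.406, against 0.178 to 0.26 in the other groups of experiment 4. Neither Smarca4 (-0.08 ± 0.11, adjusted p = 0.595) nor Pbrm1 (-0.41 ± 0.22, adjusted p = 0.161) passed.

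Of 30 primary genes 1 rose, 27 fell and 2 did not pass (1 and 28 adjusted over the list alone, camera adjusted p = 8.11e-20, or 0.00576 with an estimated correlation). Traf1 (-3.56 ± 0.14) and the NF-kB subunit gene Rel (-2.62 ± 0.14) fell. Of 21 secondary genes 0 rose, 16 fell and 5 did not pass (camera adjusted p = 3.85e-13, or 0.00979 with an estimated correlation). The TLR4 signalling genes Ticam1 (-2.27 ± 0.10), Irak2 (-2.05 ± 0.07) and Tlr4 (-1.07 ± 0.15) fell. Of the 28 measured, 0 rose, 13 fell and 15 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 1.44e-06, or 0.301 with an estimated correlation). Of 14 inflammasome genes 1 rose, 9 fell and 4 did not pass (camera adjusted p = 0.000272, or 0.368 with an estimated correlation). Mefv (-3.27 ± 0.14) and Nlrp3 (-3.04 ± 0.08) fell. The heat shock genes Dnajb1 (4.10 ± 0.10), Hspa1a (3.06 ± 0.16) and Hspa1b (2.77 ± 0.18) rose. Of the 14 measured, 9 rose, 0 fell and 5 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 2.25e-05, or 0.301 with an estimated correlation). Immediate early genes split, with Klf2 (2.26 ± 0.09) and Jun (2.04 ± 0.12) higher and Klf6 (-1.71 ± 0.08) lower. Of the 23 measured, 12 rose, 10 fell and 1 did not pass (camera adjusted p = 0.812). Of 39 interferon response genes 3 rose, 9 fell and 27 did not pass (camera adjusted p = 0.0896). Of 13 alternative activation genes 1 rose, 5 fell and 7 did not pass (1 and 6 adjusted over the list alone, camera adjusted p = 0.0165, or 0.302 with an estimated correlation). Egr2 (-1.55 ± 0.12) fell and Klf4 (2.11 ± 0.21) rose. Hmox1 (2.29 ± 0.09) rose and Mki67 (-2.75 ± 0.15) fell. Neither stands for its list. Of the 531 induced genes 56 rose and 397 fell (median -0.94 against 0.06; adjusted p = 1.87e-49, adjusted p = 0.00155 with an estimated correlation).
The effect differed between 60 and 20 min for 1746 genes, 995 higher and 751 lower (840 and 981 after median scaling). Tnf (1.42 ± 0.12) moved toward the control level, Prdm1 (-4.13 ± 0.13) away from it, and Dnajb1 (3.87 ± 0.14) rose. Il12b, Il6 and Arc lay too near the floor at 20 min to compare. In this comparison 12 genes, Egr1 and Nfkbia among them, were lower at 20 min and higher at 60 min. Counts at 60 min were 2390 higher and 1568 lower, 2003 and 2104 after median scaling (60.4% and 48.8% higher), and 439 and 744 in the authors' deposited table. The difference between times took 3775 genes without BRM014 replicate 2 at 60 min. The total at 60 min was lower without 60 min control replicate 1 and higher without BRM014 replicate 2.

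BRDK98 at 60 min also lowered induced cytokine transcripts, and 22 of 30 primary NF-kB genes fell. Il12b (-5.05 ± 0.10, 0.234 ± 0.0884 against 39.9 ± 2.86 TPM), Acod1 (-4.63 ± 0.18), Csf2 (-4.03 ± 0.12), Cxcl1 (-3.79 ± 0.17), Il6 (-3.35 ± 0.14), Ifnb1 (-3.18 ± 0.15), Ptgs2 (-3.10 ± 0.20), Ccl5 (-2.72 ± 0.15), Il10 (-2.26 ± 0.21), Cxcl10 (-1.71 ± 0.25), Tnf (-1.61 ± 0.08) and Il1b (-4.25 ± 0.13) fell. Nos2 (-0.08 ± 0.11, adjusted p = 0.711) lay near the floor. Rgs2 (3.90 ± 0.09), the RNA demethylase gene Alkbh5 (4.29 ± 0.14), Hspa1a (3.41 ± 0.16), Fosb (3.37 ± 0.30), Mt1 (3.32 ± 0.14) and Srxn1 (2.62 ± 0.09) rose. No change passed in Smarca4 (0.10 ± 0.11, adjusted p = 0.643) or Pbrm1 (0.17 ± 0.22, adjusted p = 0.706).

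Of 30 primary genes 0 rose, 22 fell and 8 did not pass (0 and 23 adjusted over the list alone, camera adjusted p = 4.69e-36, or 0.00155 with an estimated correlation). Of 21 secondary genes 0 rose, 15 fell and 6 did not pass (0 and 16 adjusted over the list alone, camera adjusted p = 1.24e-27, or 0.00155 with an estimated correlation). Of 39 interferon response genes 1 rose, 22 fell and 16 did not pass (2 and 31 adjusted over the list alone, camera adjusted p = 4.43e-17, or 0.415 with an estimated correlation). Cmpk2 (-1.28 ± 0.30) fell. The immediate early genes Egr3 (2.68 ± 0.19) and Nr4a2 (2.55 ± 0.10) rose. Of the 23 measured, 15 rose, 5 fell and 3 did not pass (camera adjusted p = 2.67e-05, or 0.405 with an estimated correlation). Of 14 heat shock genes 5 rose, 0 fell and 9 did not pass (camera adjusted p = 0.000406, or 0.368 with an estimated correlation). Dnajb1 (1.36 ± 0.10) rose. Of 13 NRF2 targets 6 rose, 0 fell and 7 did not pass (camera adjusted p = 0.00192, or 0.341 with an estimated correlation). Osgin1 (1.66 ± 0.09) rose. Of 23 cholesterol synthesis genes 6 rose, 0 fell and 17 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.00157, or 0.301 with an estimated correlation). Of 8 dendritic cell markers 0 rose, 4 fell and 4 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.000654, or 0.0433 with an estimated correlation). Bst2 (-0.53 ± 0.15) fell. Of the 531 induced genes 73 rose and 296 fell (median -0.58 against 0.08; adjusted p = 4.56e-51, adjusted p = 0.00155 with an estimated correlation).
Between 20 and 60 min the effect differed for 838 genes, 476 higher and 362 lower. Rgs2 (4.72 ± 0.12) and Alkbh5 (4.42 ± 0.20) moved higher. Il12b, Il6 and Ifnb1 lay too near the floor at 20 min to compare. Of 31 genes called at both times in opposite directions 29 were lower at 20 min and higher at 60 min, with Fos, Nr4a1 and Zfp36 among the 31. Counts at 60 min were 900 higher and 642 lower, 703 and 848 after median scaling (58.4% and 45.3% higher). The total was 913 without 60 min control replicate 1, and the authors' deposited table has 599 and 862.

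**Figure D2:**
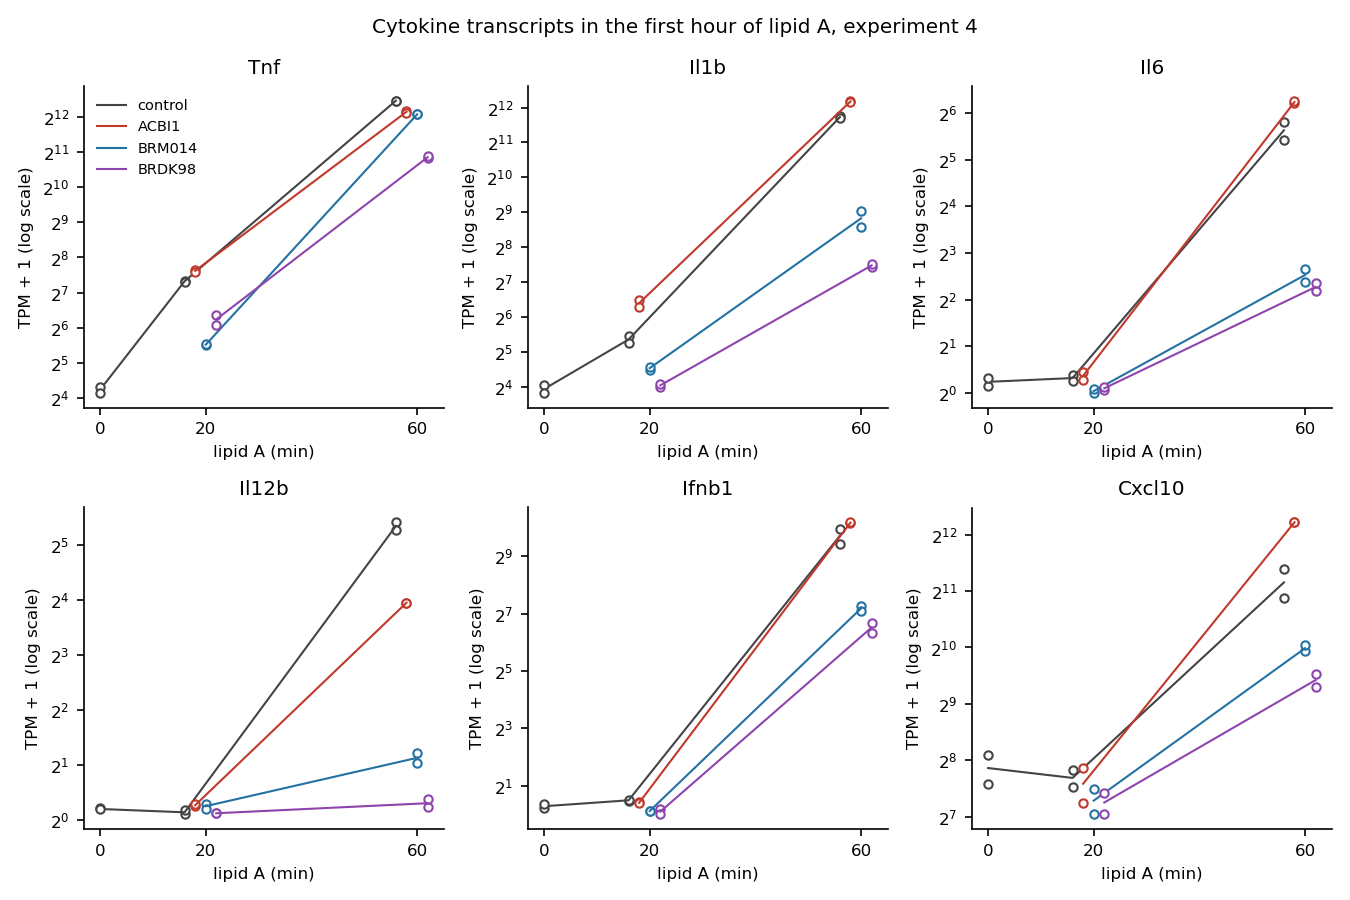
Level of 6 cytokine transcripts in each library of experiment 4 (y axis, TPM plus 1, log scale; x axis, minutes of lipid A, groups set slightly apart; circles, libraries; lines, group means). At 60 min Il12b averages 39.9 TPM in the control, 14.5 with ACBI1, 1.19 with BRM014 and 0.234 with BRDK98, and Il6 averages 48.5, 74.3, 4.77 and 3.83 TPM.

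Direct tests between compounds at 60 min, with 2 libraries each, separate ACBI1 from the other compounds. With BRM014 there was less Il12b (-2.83 ± 0.10), Il6 (-3.71 ± 0.14), Ifnb1 (-2.99 ± 0.15), Ccl5 (-3.05 ± 0.15), Isg20 (-3.00 ± 0.24) and Irf7 (-1.79 ± 0.21) than with ACBI1. Tnf (-0.07, 95% interval -0.26 to 0.11, adjusted p = 0.454) did not pass.
With BRDK98 there was less Il12b (-3.65 ± 0.10), Il6 (-3.96 ± 0.14), Ifnb1 (-3.67 ± 0.15), Tnf (-1.30 ± 0.08), Isg20 (-3.68 ± 0.24) and Irf7 (-3.12 ± 0.21) than with ACBI1.
BRDK98 gave less Ptgs2 (-2.42 ± 0.20), Tnf (-1.22 ± 0.08), Il12b (-0.83 ± 0.10) and Ifnb1 (-0.67 ± 0.15) and more Il10 (0.88 ± 0.21) than BRM014. Il12b averaged 0.234 TPM, near the floor, against 1.19 TPM, so the size of its change depends on the 1 added to TPM. Nos2 (0.019 against 0.0425 TPM) was too low to compare. Il6 (-0.25, 95% interval -0.55 to 0.04, adjusted p = 0.175), Cxcl10 (-0.57, 95% interval -1.12 to -0.02, adjusted p = 0.11) and Isg20 (-0.68, 95% interval -1.20 to -0.16, adjusted p = 0.0526) did not pass. Counts higher and lower were 4982 and 2264 (3363 and 3337 after median scaling) for BRM014 against ACBI1. BRDK98 gave 4972 and 1646 (2485 and 2567) against ACBI1 and 1759 and 1461 (1830 and 1756) against BRM014. All-gene medians against ACBI1 were 0.20 and 0.24. Counts at 20 min were 8 and 40, 68 and 136, and 54 and 71.

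Shared control libraries also tie the compound effects of experiment 4. Across genes, at 20 min r was 0.67 for ACBI1 and BRM014, 0.53 for ACBI1 and BRDK98 and 0.63 for BRM014 and BRDK98, against 0.50, 0.50 and 0.51 in simulated unchanged groups. Over the 67 and 180 genes called in either contrast the first 2 were 0.37 and 0.16. At 60 min ACBI1 parted from the others. There r was -0.07 with BRM014 (0.03 without control replicate 1) and -0.13 with BRDK98 (-0.03 without it; covariances of -0.017 and -0.025 against 0.013 and 0.012 simulated). BRM014 and BRDK98 gave 0.49 (covariance 0.112 against 0.013), with 290 genes higher with both and 460 lower with both where 117.9 and 86.6 would fall together by number alone. Between experiments, which share no libraries, the 60 min and 4 hr effects correlated at -0.17 for ACBI1, 0.26 for BRM014 and 0.24 for BRDK98. Arid1a loss at 4 hr correlated with ACBI1, BRM014 and BRDK98 at 4 hr at 0.14, 0.25 and 0.32, and at 1 hr with the compounds at 60 min at 0.12, 0.32 and 0.19. Pbrm1 loss gave -0.20, -0.17 and -0.21 with the compounds at 4 hr and -0.12 with Arid1a loss at 4 hr, and -0.08, -0.04, -0.12 and -0.06 without 4 hr control replicate 2 of experiment 3. Genes are not independent replicates in any of these.

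**Figure D3:**
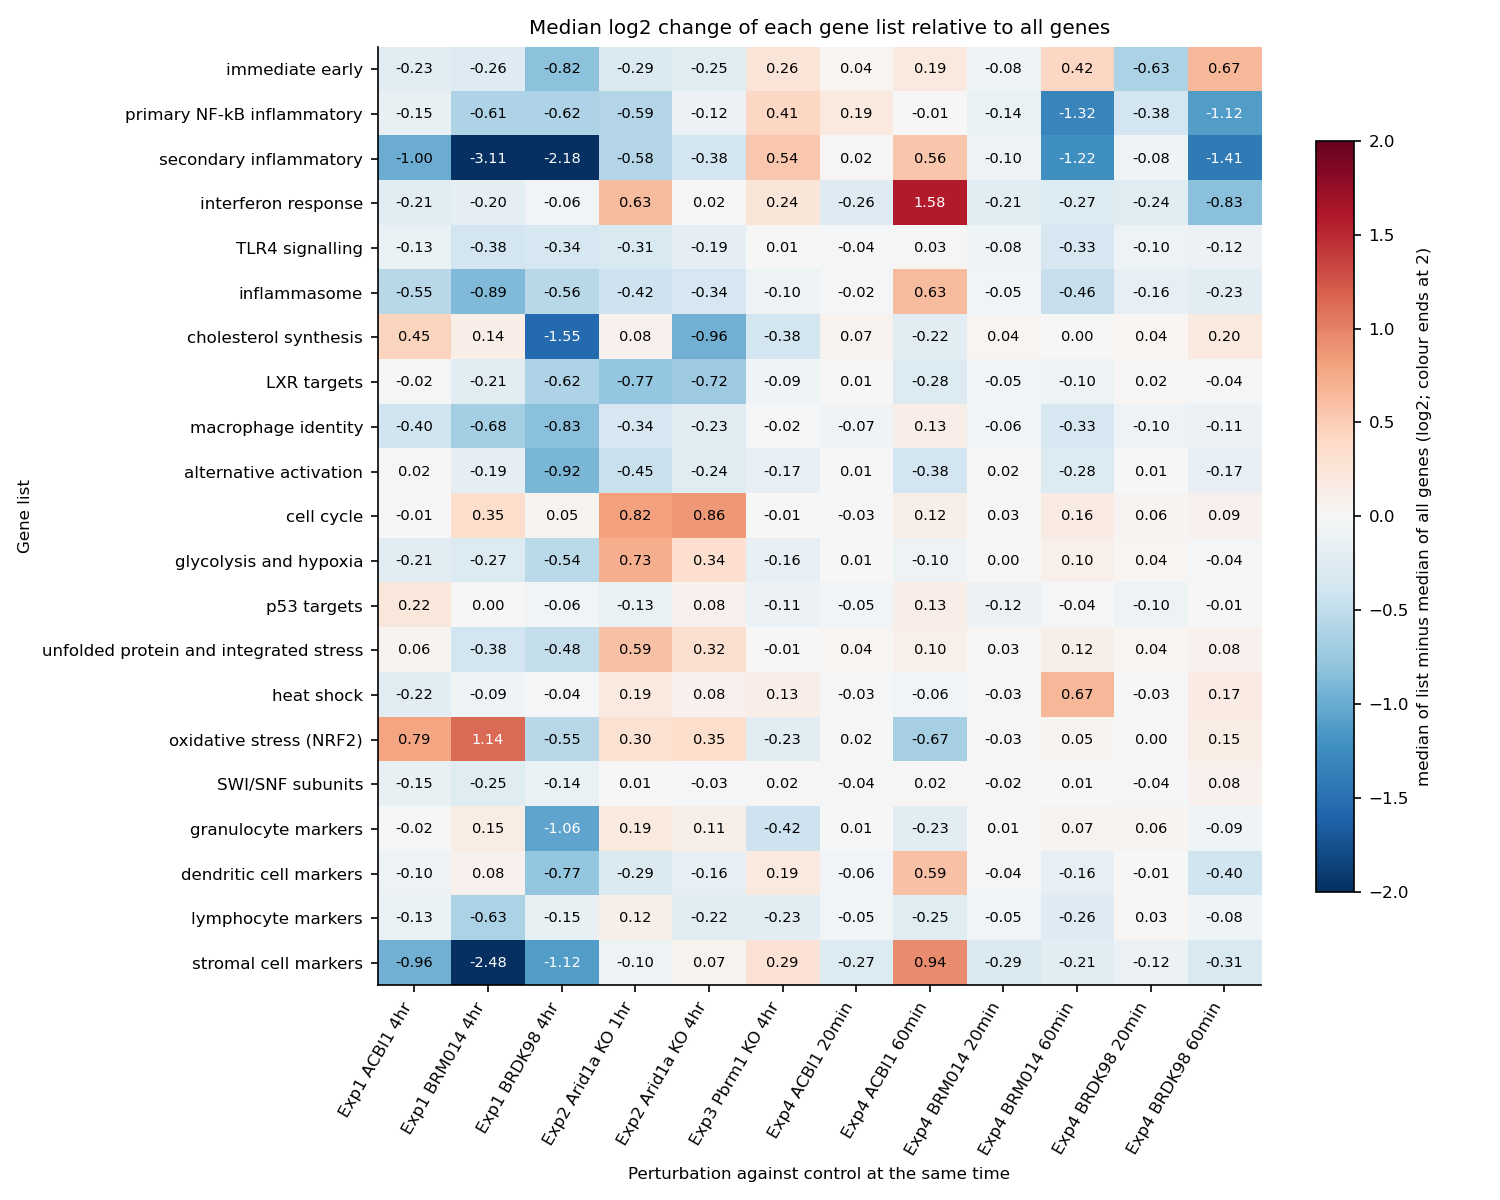
Median log2 change of each gene list minus the median of all genes (colour and number) for each list (rows) and each perturbation against control at the same time (columns). Secondary inflammatory genes fall by 3.11 with BRM014 at 4 hr, and interferon response genes rise by 1.58 with ACBI1 at 60 min.

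**Figure D4:**
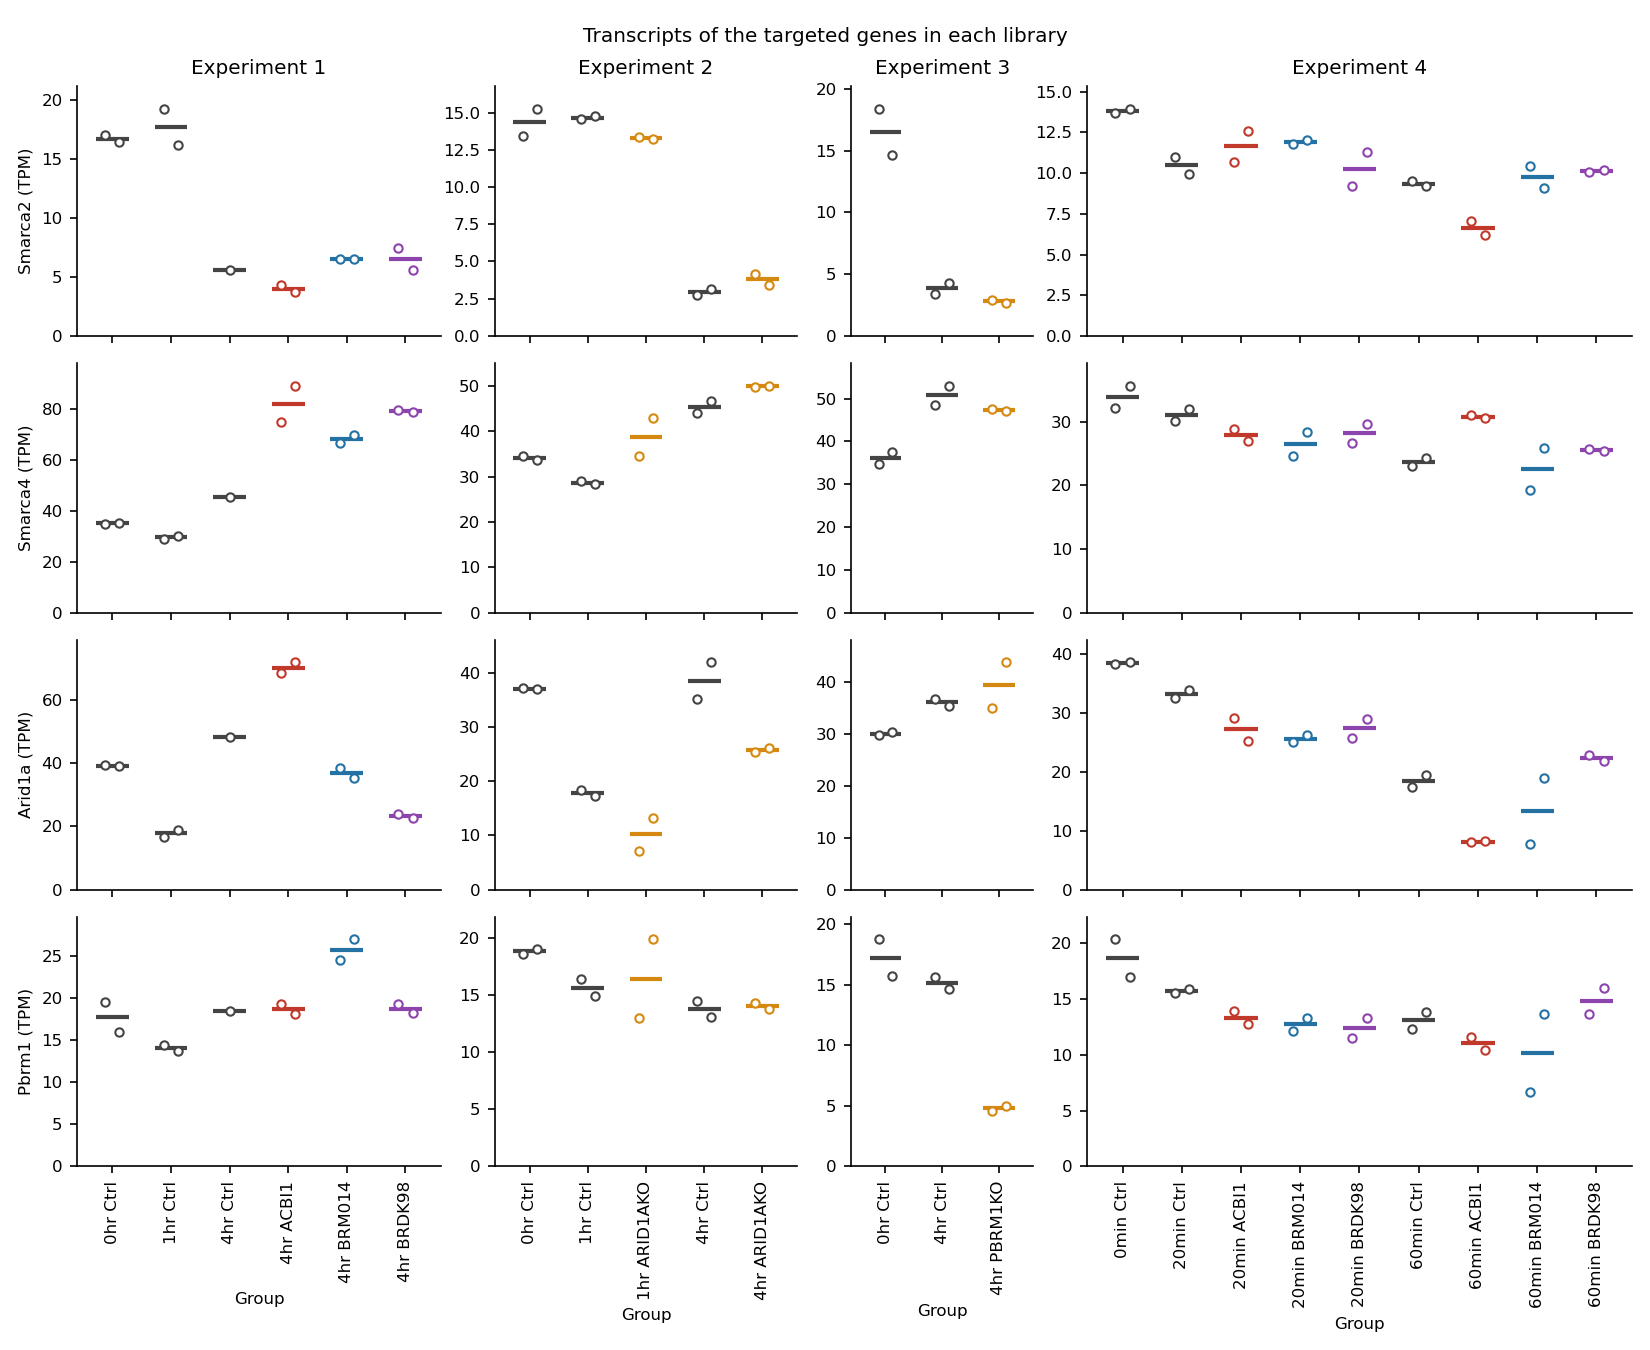
Transcript level of the 4 targeted genes in each library (y axis, TPM, from 0; x axis, group; circles, libraries; bars, group means) of the 4 experiments (columns). Pbrm1 averages 4.79 TPM in knockout and 15.2 TPM in control libraries at 4 hr, and Arid1a transcript remains in all 4 Arid1a knockout libraries.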

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

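In the first pattern the control response of experiment 3 was chosen as a stand-in before the result was seen. Experiment 1 has a single 4 hr control library, and an atypical library could by itself make all 3 compounds look alike. Replacing its stimulus response by that of experiment 3 kept the sign of 3268 of 4051 genes called for ACBI1 (80.7%), 4523 of 5114 for BRM014 (88.4%) and 3610 of 4199 for BRDK98 (86%). The values for BRM014 and BRDK98 argue against an atypical control as the source of most calls. For ACBI1 and for calls that changed sign this stays open. Differences in mice or handling between experiments, or control replicate 2 of experiment 3, which held less Il6 (58.5 against 231 TPM), may also lower these values.

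In the second pattern the tests of the 20 min level and of scaling were chosen only after seeing the result, and the test of stimulation time before it. Interferon response genes were higher with ACBI1 at 60 min, which could come from genes that were already higher, from scaling, or from a longer effective stimulation. Their median at 20 min was -0.26, which argues against genes already higher, and on scaled TPM at 60 min it was 1.61, which argues against scaling. Across 10865 genes the ACBI1 effect correlated at r = 0.51 with the change of control cells from 1 to 4 hr in experiment 1 (0.49 without the list), in line with a longer effective stimulation of those libraries, though a direct effect of ACBI1 on interferon genes may give the same.

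In the third pattern both tests were chosen only after seeing the result. Leaving out control replicate 1 of experiment 3 gave 2178 genes for Pbrm1 loss and leaving out control replicate 2 gave 12. Each of these fits has 1 control library, with the spread taken from the other groups, and which control is typical is not known. The difference between the control replicates correlated at r = -0.49 with the 4 hr lipid A response across 10906 genes (-0.02 for the knockout pair), so loss of Pbrm1, a replicate 2 that responded less and a control that differs for another reason cannot be told apart.

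A hypothesis, with tests chosen only after seeing the result, is that the perturbations act opposite to the stimulus response. The effects correlated with the stimulus response at -0.38 for ACBI1, -0.52 for BRM014 and -0.47 for BRDK98 at 4 hr and at -0.44 for BRM014 and -0.42 for BRDK98 at 60 min, in line with it. Arid1a loss gave -0.20 at 1 hr and -0.12 at 4 hr, which leave it open, and ACBI1 at 60 min gave -0.01, which argues against it.

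The Arid1a effect differed between 4 and 1 hr for 1982 genes, among them Il6 (by 2.10) and Il12b (by 3.76), which were lower at 1 hr and higher at 4 hr. Between 60 and 20 min the number was 3112 for ACBI1, 1746 for BRM014 and 838 for BRDK98.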

How the results depend on the processing

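Groups hold 2 libraries or fewer, so no gap test for a divergent library (4 or more per group) and no other splits of the samples (3 or more) were run, and depth limits calls near 0.065 to 0.298 TPM. A minimum absolute log2 change of 1 lowered the counts by construction: lipid A 1848 at 1 hr in experiment 1, 5193 in experiment 3, 49 at 20 min and 1046 at 60 min; LPS 1126 at 1 hr and 4909 at 4 hr; at 4 hr ACBI1 1591, BRM014 3311, BRDK98 2871, BRM014 against ACBI1 928, BRDK98 against ACBI1 1557 and against BRM014 1602; Arid1a loss 767 at 1 hr, 475 at 4 hr and 562 for the difference; ACBI1, BRM014 and BRDK98 2, 15 and 41 at 20 min, 517, 631 and 355 at 60 min, and 623, 565 and 341 for the difference. Median scaling gave 4806 genes for lipid A at 1 hr in experiment 1, 4259 at 60 min and 1 for Pbrm1 loss. Genes called on both scalings numbered 3718 for lipid A at 1 hr, 3069 at 60 min, 4287 for BRDK98 at 4 hr, 3006 for ACBI1 at 60 min and 1 for Pbrm1 loss. With voom on recovered reads lipid A at 60 min gave 4092 genes and Pbrm1 loss 2; at 4 hr Pbrm1 (-0.35, adjusted p = 0.0305) with ACBI1 and Il6 (-0.53, adjusted p = 0.00684) and Pbrm1 (-0.63, adjusted p = 0.00035) with BRDK98 were called lower, while Il12b (-0.02) with ACBI1 and Pbrm1 (-0.11) and Smarca4 (0) with BRM014 did not pass (adjusted p = 0.919, 0.508 and 0.995). Median scaling gave Pbrm1 -0.02 with BRM014 (adjusted p = 0.898) and -0.53 with BRDK98 (adjusted p = 0.00525). Pbrm1 loss gave 12 genes at a pseudocount of 0.1, 2 with no filter and 4 without trend or robust moderation; ACBI1 at 20 min gave 13 without trend or robust moderation. Apart from the fold minimum the cause was not tested.

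A replicate block gave 0 genes for Pbrm1 loss and 15 for ACBI1 at 20 min; same-number replicates correlated across groups at -0.04 to 0.17, -0.09 to 0.15, 0.01 to 0.23 and -0.24 to 0.24 in experiments 1 to 4. Leaving out single libraries gave ranges of 3460 to 3620 for LPS at 1 hr, 2763 to 5414 for Arid1a loss at 1 hr, 2005 to 2328 at 4 hr and 961 to 3424 for the difference, 0 to 2178 for Pbrm1 loss, 54 to 538 for lipid A at 20 min, 0 to 8, 22 to 24 and 78 to 97 for ACBI1, BRM014 and BRDK98 at 20 min, 2672 to 3684, 2528 to 6294 and 913 to 1222 at 60 min, and 1956 to 2690, 1173 to 3775 and 569 to 706 for the differences. Among named genes, 112 such values lost their call, 6 gained one and 1592 did not change. The induced set p ranged over 7.44e-05 to 0.0709 for Arid1a loss at 4 hr and 1.29e-05 to 0.0518 for ACBI1 at 20 min.

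With an estimated correlation the induced set p was 0.164 for ACBI1, 0.085 for BRM014, 0.1 for BRDK98 and 0.164 for Pbrm1 loss at 4 hr, 0.1 and 0.376 for Arid1a loss at 1 and 4 hr, and 0.28 for ACBI1 and 0.143 for BRM014 at 20 min; of 252 list results 73 lost their call and 179 did not change. Over called genes only, r at 20 min was 0.37 for ACBI1 with BRM014 and 0.16 with BRDK98. A pseudocount of 0.1 gave -0.02 for ACBI1 and BRDK98 at 60 min and 0.51 for BRM014 and BRDK98 at 20 min. Leaving out libraries gave ranges of -0.10 to 0.03 for ACBI1 and BRM014 at 60 min, which crosses 0, -0.16 to -0.03 for ACBI1 and BRDK98, and, for Pbrm1 loss with ACBI1, BRM014 and BRDK98 at 4 hr, -0.22 to -0.08, -0.19 to -0.04 and -0.21 to -0.12.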
